A study of Mus musculus with 12 samples.

How the data were processed

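RNA of gonadal white adipose tissue was measured in 12 libraries of WT mice and from mice that lack Bnip3 in macrophages (MKO), on normal chow (NCD) or a high-fat diet (HFD), with 3 biological replicates per group. Per the labels' protocols the libraries were made with a stranded mRNA kit and the mice were on their diet for 12 weeks from 8 weeks of age. Per the submitters' processing notes, bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0, StringTie 1.3.4d and DESeq2 were used with the mouse genome mm10. The versions of Trimmomatic and DESeq2 are not given.

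The deposited table holds, per the file headers, raw read counts per gene and library, which are the values tested here. It also holds the authors' FPKM, TPM and normalized log2 expression values per library. Its log2 group means are minus infinity where all libraries of a group read 0. For each genotype comparison the authors deposited a signed fold change, its standard error and a test statistic, which are a score per gene. The authors' deposited p-values, raw and adjusted, are read here only to count the genes they call and for Bnip3.

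The count table holds 32238 genes, of which 20297 passed the filterByExpr function of edgeR by group and were tested. Gene positions and biotypes were taken from the RefSeq annotation of the same genome by gene identifier, which matched 20246 of the tested genes. Library totals were 52.9 to 72.7 M counts, no 2 libraries had identical columns, and no gene or library was removed by hand. In R 4.3.3, edgeR 4.0.16 was used with TMM size factors, 1 fit of all 12 libraries by group, robust quasi-likelihood estimation and the quasi-likelihood F test. Adjusted p is by Benjamini-Hochberg over the genes tested, with a threshold of 0.05 for every test. The standard error (SE) of a log2 fold change is its absolute value over the square root of the F statistic. Group values are the mean and standard deviation (SD) of CPM with TMM library sizes, n = 3. Where every library of a group reads 0, the fold is a bound that puts 3 counts in that group, and where a group holds 1 to 3 counts the ratio of counts has a 95% counting interval.

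The 6 comparisons are MKO against WT on NCD, MKO against WT on HFD, HFD against NCD in WT, HFD against NCD in MKO, the difference of the diet effects between genotypes (interaction), and MKO against WT averaged over diets. For each, 30 gene lists written by hand were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists with at least 5 tested members. The lists cover macrophage markers, lipid-associated macrophage genes, resident and alternatively activated macrophage genes, inflammatory cytokines and chemokines, interferon-stimulated genes, markers of monocytes and neutrophils, dendritic cells, T and NK cells, B cells and mast cells, adipocyte identity, lipogenesis, lipolysis, fatty acid oxidation, oxidative phosphorylation, mitophagy and autophagy without Bnip3, glycolysis and hypoxia response, insulin signalling, extracellular matrix and fibrosis, thermogenic genes, oxidative stress response, unfolded protein response, cell cycle, markers of endothelium, fibroblasts and progenitors, mesothelium, epididymis, skeletal muscle and red blood cells, and immediate early and heat shock genes. A list's median log2 fold change is over its tested members, and members are also counted with p adjusted over the list alone.

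The genes named are Bnip3 and, per comparison, the 5 largest rises and the 5 largest falls past the threshold with a mean of at least 1 CPM and groups that do not overlap, the 4 members of each called list and the 2 members of each other list with the smallest p, and a panel of Lep, Adipoq, Ccl2, Tnf, Il1b, Adgre1, Itgax, Trem2, Mrc1 and Lyz2. Where fewer genes pass, all that pass qualify, and the text names a subset of those the rule gives. The rule leaves out predicted genes, clones without a name and immunoglobulin or T cell receptor segments, and the condition that groups do not overlap is not used for the interaction and the average over diets. Genes named in the closing section for their chromosome or for shared read sequence were chosen after their values were seen. The groups, comparisons, main test, lists, naming rule and alternatives were fixed before the data were examined, apart from the alternatives named as added later in the closing section.

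Alternatives were RLE and upper-quartile size factors, no count filter, a filter of 1 CPM, no robust spread, DESeq2 1.42.0, limma-voom with and without sample weights, fits of only the 6 libraries compared, a minimum fold of 2, a block by replicate number, camera with an estimated correlation, fry, and fits that leave out 1 library. The test was checked on simulated data (closing section). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.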

Results

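Gonadal white adipose tissue, the fat that lies along the epididymis, was profiled by RNA sequencing in 12 libraries of WT mice and of mice that lack Bnip3 in macrophages (MKO), on normal chow (NCD) or a high-fat diet (HFD). Bnip3 encodes a protein of the outer mitochondrial membrane that recruits the autophagy machinery to mitochondria. The design asks how 12 weeks of HFD, and the loss of Bnip3 in macrophages on each diet, change this tissue. Each group holds 3 biological replicates (rep). Unless stated otherwise, levels are mean ± SD in CPM (n = 3 libraries), changes are log2 fold changes with their standard error (SE), and adjusted p for genes is from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 20297 genes. Members of a gene list counted in-list have p adjusted over that list alone. The camera test of a list has a preset correlation between genes, and its adjusted p marked estimated has a correlation estimated from the data. Every library is male, with Xist, transcribed from the inactive X, at 0.514 CPM or less and the Y-linked Ddx3y at 76.0 to 146 CPM.

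Bnip3 itself was not lower in MKO fat on either diet. It read 392, 568 and 475 CPM in WT NCD and 547, 811 and 563 CPM in MKO NCD. On HFD it read 418, 358 and 410 CPM in WT and 446, 415 and 476 CPM in MKO. The log2 fold change of MKO against WT was 0.42, SE 0.17, adjusted p = 0.210 on NCD and 0.17, SE 0.17, adjusted p = 0.786 on HFD. Averaged over diets it was 0.30, SE 0.12, adjusted p = 0.179. HFD against NCD gave -0.28, SE 0.17, adjusted p = 0.321 in WT and -0.52, SE 0.17, adjusted p = 0.170 in MKO. The interaction was -0.25, SE 0.25, adjusted p = 0.792. The deletion is in macrophages only. Whole-gene counts of whole tissue do not separate macrophage transcripts from those of other cells, so these values do not check the genotype labels.

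The WT NCD libraries carried transcripts of the epididymis that the other 9 libraries nearly lacked. The 9 measured epididymis markers include Crisp1, which encodes a sperm-binding secretory protein. Their summed level was 4788, 5654 and 5628 CPM in WT NCD and 16.97, 0 and 2.64 CPM in MKO NCD. It was 0.859 CPM or less in each HFD library. MKO NCD rep 2 read 0 for 57.3% of the genes in the table, against 15.6 to 38.3% in the other libraries. It also read 0 for 702 genes that had at least 100 counts in each of the other 11 libraries.

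**Figure D1:**
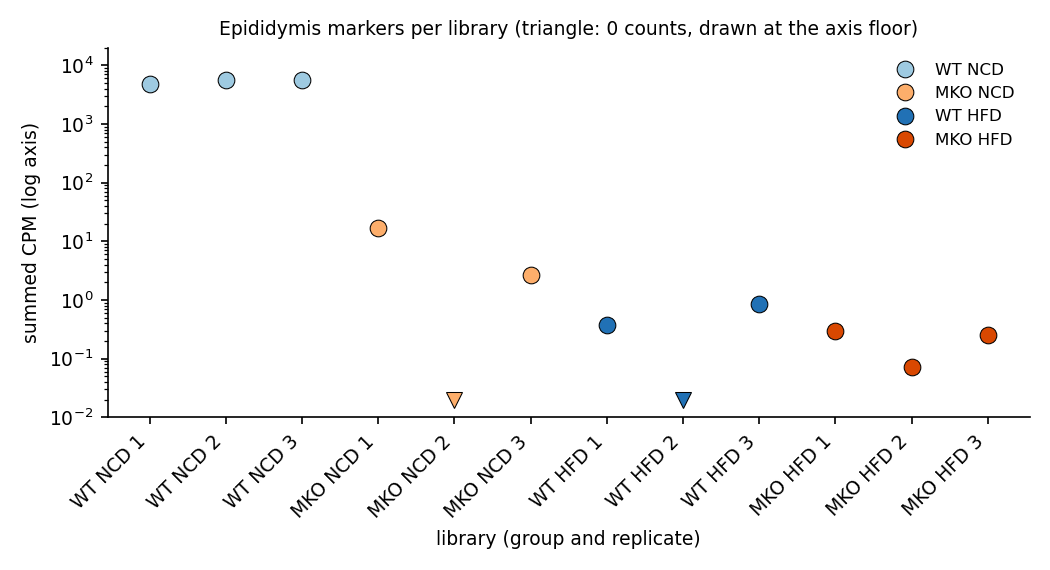
Summed level of the epididymis markers (CPM, log axis), 1 point per library, coloured by group (a triangle marks a library with 0 counts). The WT NCD libraries lie at 4788 to 5654 CPM and all others at 16.97 CPM or less.

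After 12 weeks of HFD the gonadal fat of WT mice carried more transcripts of matrix, macrophages and dividing cells. Of 19 tested genes of extracellular matrix and fibrosis, 16 rose (17 higher and 1 lower in-list). Their median log2 fold change was 1.76 (camera adjusted p = 7.28e-13, 0.228 estimated). Col3a1, a fibrillar collagen, went from 614 ± 126 to 2819 ± 641 CPM (log2 fold change 2.2, SE 0.22, adjusted p = 2.27e-04). Tgfb1, the growth factor that drives collagen synthesis, rose from 24.96 ± 1.56 to 70.3 ± 8.16 CPM (log2 fold change 1.49, SE 0.12, adjusted p = 8.95e-05). Col5a1 (1.76, SE 0.18, adjusted p = 2.36e-04) and Col5a2 (1.76, SE 0.18, adjusted p = 2.27e-04), which set the width of collagen fibrils, rose as well. So did Lum, a proteoglycan that binds them (2.92, SE 0.37, adjusted p = 5.66e-04). Markers of fibroblasts and progenitors moved the same way, with 5 higher and 1 lower of 10 (median 0.88, camera adjusted p = 0.0102, 0.333 estimated). Cd34, a surface protein of progenitors, was among them (0.82, SE 0.14, adjusted p = 0.00309). The lower count was 0 without WT HFD rep 2.

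Macrophage markers rose in 14 of 18 genes (14 in-list, median 2.16, camera adjusted p = 7.34e-10, 0.287 estimated). Lyz2, the macrophage lysozyme, rose from 292 ± 175 to 1335 ± 171 CPM (log2 fold change 2.19, SE 0.40, adjusted p = 0.00381). Adgre1, which encodes the F4/80 antigen, rose from 26.1 ± 11.9 to 212 ± 81.1 CPM (log2 fold change 3.02, SE 0.55, adjusted p = 0.00385). Csf1r, the receptor for the macrophage growth factor, rose too (1.96, SE 0.31, adjusted p = 0.00172). Mpeg1, a pore-forming protein of phagosomes (3.52, SE 0.55, adjusted p = 0.00172), and the protease Ctss (3.61, SE 0.56, adjusted p = 0.00170) rose as well. Lipid-associated macrophage genes rose in 14 of 17 (16 in-list, median 3.12, camera adjusted p = 2.39e-10, 0.260 estimated). Trem2, a lipid receptor that marks these cells, rose from 4.12 ± 3.14 to 104 ± 46.7 CPM (log2 fold change 4.65, SE 1.25, adjusted p = 0.0260). Fabp5, a fatty acid carrier, is of the same set (2.503, SE 0.21, adjusted p = 1.02e-04). So are the lysosomal proteases Ctsk (3.12, SE 0.35, adjusted p = 3.69e-04), Ctsb (1.63, SE 0.19, adjusted p = 3.75e-04) and Ctsd (1.84, SE 0.18, adjusted p = 2.27e-04). Without 1 library Trem2 no longer passed, at adjusted p = 0.0684 without WT HFD rep 1 and 0.0897 without WT HFD rep 2. Its adjusted p was 0.0859 without WT NCD rep 1 and 0.0831 without WT NCD rep 3. Trem2 was also lost with no count filter. Members of its list past the threshold numbered 9 without WT NCD rep 1, WT HFD rep 1 or WT HFD rep 2.

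Resident and alternatively activated macrophage genes rose in 5 of 16 (5 in-list, camera adjusted p = 2.40e-04, 0.292 estimated). The scavenger receptors Stab1 (1.43, SE 0.15, adjusted p = 2.61e-04) and Mrc1 (1.80, SE 0.30, adjusted p = 0.00256) are among them. Of the inflammatory cytokines and chemokines 2 rose and 1 fell of 18 (camera adjusted p = 0.0102, 0.337 estimated). Ccl2, which attracts monocytes, rose from 2.29 ± 0.776 to 19.6 ± 2.37 CPM (log2 fold change 3.09, SE 0.47, adjusted p = 0.00147). The cytokines Tnf (2.21, SE 0.74, adjusted p = 0.0641) and Il1b (-0.32, SE 1.09, adjusted p = 0.889) did not pass. Without MKO NCD rep 2 in the fit 8 of these genes were higher, and without WT NCD rep 1, WT NCD rep 3 or any 1 WT HFD library 1 was. Cell cycle genes rose in 5 of 14 (10 in-list, median 2.42, camera adjusted p = 2.12e-05, 0.287 estimated). Mki67, a protein of dividing cells, rose from 8.78 ± 2.37 to 78.0 ± 20.02 CPM (log2 fold change 3.15, SE 0.36, adjusted p = 4.04e-04). The DNA topoisomerase Top2a rose (2.72, SE 0.30, adjusted p = 3.01e-04). The cell cycle count was 3 without WT HFD rep 1 or 2 and 13 without MKO NCD rep 2.

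In the same WT fat, genes of the mature adipocyte fell. Of 16 adipocyte identity genes 8 fell and 2 rose (8 and 3 in-list, median -0.59, camera adjusted p = 0.0244, 0.503 estimated). The list call was lost without WT NCD rep 2 (camera adjusted p = 0.0634) and without MKO NCD rep 2 (camera adjusted p = 0.0772). Cfd, the secreted protease adipsin, dropped from 7121 ± 3836 to 366 ± 154 CPM (log2 fold change -4.28, SE 0.52, adjusted p = 4.98e-04). Pck1, which makes glycerol for triglyceride, fell from 1871 ± 731 to 261 ± 33.1 CPM (log2 fold change -2.84, SE 0.26, adjusted p = 1.40e-04). The adrenergic receptor Adrb3 fell (-2.55, SE 0.41, adjusted p = 0.00199). The insulin-regulated glucose transporter Slc2a4 (-1.30, SE 0.20, adjusted p = 0.00169) and the insulin receptor substrate Irs1 (-1.19, SE 0.13, adjusted p = 3.69e-04) fell. The insulin signalling list had 5 lower of 12 and did not pass as a group (camera adjusted p = 0.0683). Leptin (Lep), the hormone that reports fat mass, rose from 744 ± 241 to 4742 ± 536 CPM (log2 fold change 2.67, SE 0.34, adjusted p = 5.82e-04). Adiponectin (Adipoq) did not pass (-0.58, SE 0.27, adjusted p = 0.162). Lipogenesis genes went both ways, 5 higher and 5 lower of 16 (camera adjusted p = 0.328). Acss2, which makes acetyl-CoA (1.42, SE 0.18, adjusted p = 6.03e-04), and malic enzyme Me1 (1.61, SE 0.17, adjusted p = 2.82e-04) rose. Adipocyte genes that rose numbered 0 without WT HFD rep 1 and 1 without WT NCD rep 1 or WT HFD rep 2. Lipolysis genes did not pass as a group (1 higher and 4 lower of 10, camera adjusted p = 0.0632).

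Fatty acid oxidation genes rose in 7 of 14, with 1 lower (9 and 2 in-list, camera adjusted p = 0.00124, 0.333 estimated). The mitochondrial dehydrogenases Acadl (1.13, SE 0.16, adjusted p = 0.00114) and Hadha (0.75, SE 0.12, adjusted p = 0.00172) rose. The lower count was 2 without MKO NCD rep 2 and 0 without any 1 WT library except WT NCD rep 3. Glycolysis and hypoxia-response genes had 7 higher and 2 lower of 15 (camera adjusted p = 0.0255, 0.337 estimated). The enzymes Tpi1 (1.29, SE 0.13, adjusted p = 2.27e-04) and Ldha (0.95, SE 0.11, adjusted p = 4.69e-04) rose. The lower count was 1 without WT HFD rep 1. Interferon-stimulated genes rose in 8 of 15 (9 in-list, camera adjusted p = 5.48e-04, 0.260 estimated). The nucleic acid sensor Zbp1 (1.503, SE 0.34, adjusted p = 0.0123) rose. This count was 0, 3 and 4 without WT NCD rep 1, 2 and 3, and 2, 2 and 1 without WT HFD rep 1, 2 and 3. Zbp1 was lost without WT HFD rep 3 (adjusted p = 0.0584) or WT NCD rep 1 (0.0524). Dendritic cell markers (1 of 9 higher, camera adjusted p = 0.0169, 0.287 estimated) moved up. Irf8, a factor of dendritic cell development, rose (2.48, SE 0.30, adjusted p = 4.97e-04). Monocyte and neutrophil markers (2 higher and 1 lower of 8, camera adjusted p = 0.0273, 0.292 estimated) moved up too, and the chemokine receptor Ccr2 rose (1.92, SE 0.34, adjusted p = 0.00346). The higher count was 1 without any 1 WT library and 5 without MKO NCD rep 2. Thermogenic genes had 4 higher of 10 (camera adjusted p = 0.0265, 0.260 estimated), and 2 without any 1 WT library except WT HFD rep 3. Endothelial markers had 1 of 10 higher (camera adjusted p = 0.0112, 0.503 estimated, camera adjusted p = 0.0842 without WT NCD rep 2). It is the tight junction protein Cldn5 (0.86, SE 0.22, adjusted p = 0.0209), which was lost without WT HFD rep 3 (adjusted p = 0.0793) and without WT NCD rep 2 (adjusted p = 0.0685). Without MKO NCD rep 2, 4 endothelial and 3 dendritic cell markers were higher.

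The largest rises on HFD in WT began at low levels. Tph2, which makes serotonin, went from 0.362 ± 0.109 to 223 ± 32.5 CPM (log2 fold change 9.27, SE 1.31, adjusted p = 0.00103). The proton channel Otop1 rose (7.40, SE 1.56, adjusted p = 0.00821). Myostatin (Mstn), a brake on muscle growth, rose (7.10, SE 1.57, adjusted p = 0.0106). The ubiquitin-like Ubd rose (6.77, SE 1.45, adjusted p = 0.00901). Among the largest falls were genes of the epididymis. Serpina1f, an epididymal serpin, was at 1036 ± 323 CPM in WT NCD and 0 in WT HFD (at least 57570-fold lower, adjusted p = 4.51e-04). Spink8, a protease inhibitor, was at least 41630-fold lower (adjusted p = 8.49e-04). Crisp1 had 2 counts over the WT HFD libraries, with a ratio of counts of 289300 (95% counting interval 80080 to 2389000, adjusted p = 7.08e-04). The epithelial keratin Krt8 fell (-4.25, SE 0.61, adjusted p = 0.00114). Plac8, a protein of epithelia and leukocytes, fell (-4.52, SE 0.83, adjusted p = 0.00394). As a list, epididymis markers fell in 3 of 6 tested genes (5 in-list, camera adjusted p = 0.00124, 0.287 estimated). The count was 1 without any 1 WT HFD library, 6 without WT NCD rep 1 and 5 without MKO NCD rep 2. Heme oxygenase (Hmox1, 2.70, SE 0.32, adjusted p = 4.96e-04) rose and the secreted peroxidase Gpx3 fell (-2.46, SE 0.29, adjusted p = 4.69e-04). Their oxidative stress list had 4 higher and 2 lower of 12 (camera adjusted p = 0.634).

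In all, 1929 genes rose and 1681 fell on HFD in WT. Called genes numbered 2031 without WT HFD rep 1 and 1884 without WT HFD rep 2. With MKO NCD rep 2 left out of the fit they numbered 6789. The WT NCD libraries here carry the epididymis transcripts given above.

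**Figure D2:**
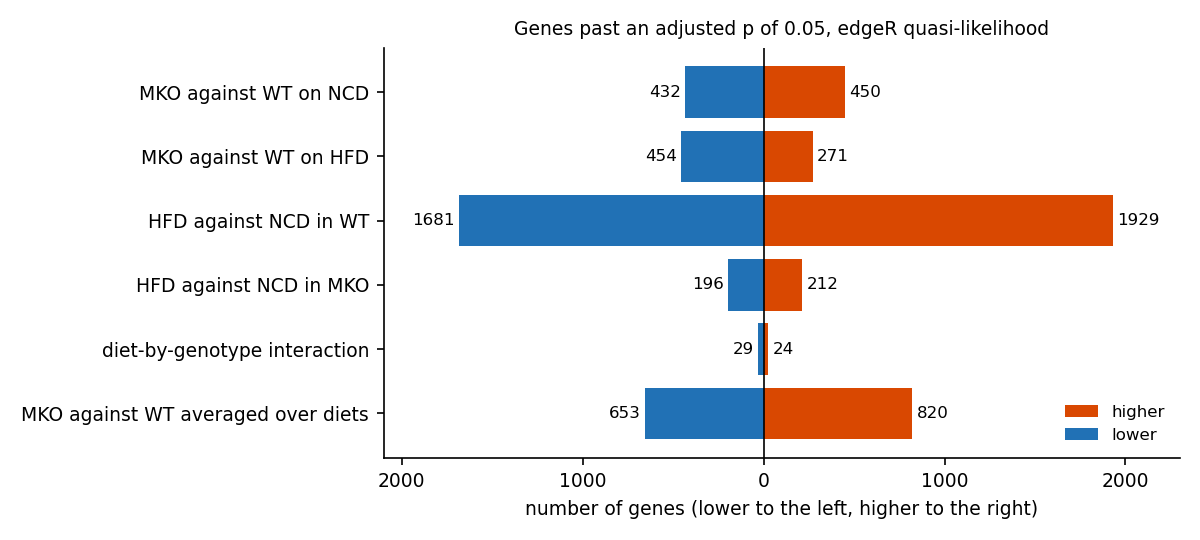
Number of genes past an adjusted p of 0.05 in each of the 6 comparisons, with rises to the right and falls to the left of 0. HFD against NCD called 3610 genes in WT and 408 in MKO.

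On HFD, MKO fat carried far fewer macrophage transcripts than WT fat. Macrophage markers fell in 14 of 18 genes (16 in-list). Their median log2 fold change was -2.14 (camera adjusted p = 8.16e-18, 0.107 estimated). Lyz2 was at 1335 ± 171 CPM in WT and 299 ± 124 CPM in MKO (log2 fold change -2.16, SE 0.40, adjusted p = 0.0195). Adgre1 was at 212 ± 81.1 and 36.1 ± 24.0 CPM (log2 fold change -2.56, SE 0.54, adjusted p = 0.0307). Mpeg1 was at 514 ± 159.6 and 69.2 ± 60.2 CPM (log2 fold change -2.89, SE 0.53, adjusted p = 0.0192). Csf1r fell as well (-1.85, SE 0.30, adjusted p = 0.0129). Lipid-associated macrophage genes fell in 7 of 17 (12 in-list, median -2.22, camera adjusted p = 3.78e-11, 0.115 estimated). The galactose-binding lectin Lgals3 (-2.45, SE 0.46, adjusted p = 0.0207) and Ctsk (-2.22, SE 0.34, adjusted p = 0.0113) fell. So did the lysosomal lipase Lipa (-2.10, SE 0.35, adjusted p = 0.0134) and the tetraspanin Cd9 (-1.69, SE 0.28, adjusted p = 0.0129). Trem2 (-3.29, SE 1.17, adjusted p = 0.184) and the integrin Itgax (-2.23, SE 1.08, adjusted p = 0.370), both markers of obese fat, did not pass. Resident and alternatively activated macrophage genes fell in 3 of 16 (4 in-list, camera adjusted p = 2.56e-04, 0.246 estimated). They are Mrc1 (-1.47, SE 0.30, adjusted p = 0.0275), the lectin Clec10a (-1.39, SE 0.27, adjusted p = 0.0228) and Stab1 (-0.76, SE 0.15, adjusted p = 0.0236).

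Matrix genes were lower in the same libraries. Extracellular matrix and fibrosis genes fell in 7 of 19 (9 in-list, median -0.66, camera adjusted p = 1.46e-08, 0.107 estimated). Col3a1 was at 2819 ± 641 CPM in WT and 1138 ± 206 CPM in MKO (log2 fold change -1.31, SE 0.22, adjusted p = 0.0129). Col1a2, a chain of type I collagen (-1.36, SE 0.20, adjusted p = 0.0108), and the gelatinase Mmp2 (-1.74, SE 0.28, adjusted p = 0.0124) fell. Lum (-2.06, SE 0.35, adjusted p = 0.0147) and Tgfb1 (-0.89, SE 0.12, adjusted p = 0.00945) fell as well. Markers of fibroblasts and progenitors fell in 2 of 10 (camera adjusted p = 0.00240, 0.246 estimated). The growth factor receptor Pdgfra is among them (-1.17, SE 0.20, adjusted p = 0.0134). Monocyte and neutrophil markers moved down (1 of 8 lower, camera adjusted p = 4.49e-04, 0.107 estimated). Ccr2 fell (-1.54, SE 0.34, adjusted p = 0.0353). Hmox1 fell too (-1.83, SE 0.31, adjusted p = 0.0143), but its oxidative stress list (2 of 12 lower) did not pass (camera adjusted p = 0.264). Mast cell markers moved down (3 of 6 lower in-list, camera adjusted p = 6.97e-04, 0.116 estimated), as did interferon-stimulated genes (median -0.37, camera adjusted p = 0.00240, 0.158 estimated). B cell markers (median -2.28, camera adjusted p = 0.00556, 0.447 estimated) and inflammatory cytokines and chemokines (median -0.80, camera adjusted p = 0.0126, 0.391 estimated) moved down too. Each of these 4 groups had 0 members past the threshold over all genes. Tnf (-0.99, SE 0.72, adjusted p = 0.625) and Ccl2 (-0.58, SE 0.43, adjusted p = 0.638) did not pass. Cell cycle genes (median -0.63, camera adjusted p = 0.0165, 0.441 estimated) lost their call without WT HFD rep 2 (camera adjusted p = 0.1001) or MKO HFD rep 3 (0.140). Red blood cell markers lost theirs (median -0.73, camera adjusted p = 0.0165, 0.441 estimated) without MKO HFD rep 3 (camera adjusted p = 0.156).

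Of the 19 called genes named in these macrophage and matrix paragraphs, 0 passed without MKO HFD rep 1 (adjusted p 0.0526 to 0.152) or MKO HFD rep 2 (0.0547 to 0.167). Tgfb1 alone passed without WT HFD rep 2, 9 genes without WT HFD rep 1, and all but Ccr2 without MKO HFD rep 3 (0.0601) or WT HFD rep 3 (0.0621). Members of the 3 macrophage lists past the threshold numbered 0 without WT HFD rep 2, MKO HFD rep 1 or MKO HFD rep 2, and 1, 3 and 1 without WT HFD rep 1. Matrix genes numbered 3 without WT HFD rep 1, 1 without WT HFD rep 2 and 0 without MKO HFD rep 1 or 2. Fibroblast markers numbered 1 without WT HFD rep 1 and 0 without WT HFD rep 2 or MKO HFD rep 1 or 2. Monocyte markers numbered 0 without any 1 HFD library. Without MKO NCD rep 2, lower members numbered 4 in the monocyte list and 2 each in the interferon and B cell lists. Adgre1 also no longer passed with no count filter. For macrophage markers each WT HFD library lay above each MKO HFD library, with mean log2 CPM of 6.60 in the lowest WT and 5.52 in the highest MKO library.

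**Figure D3:**
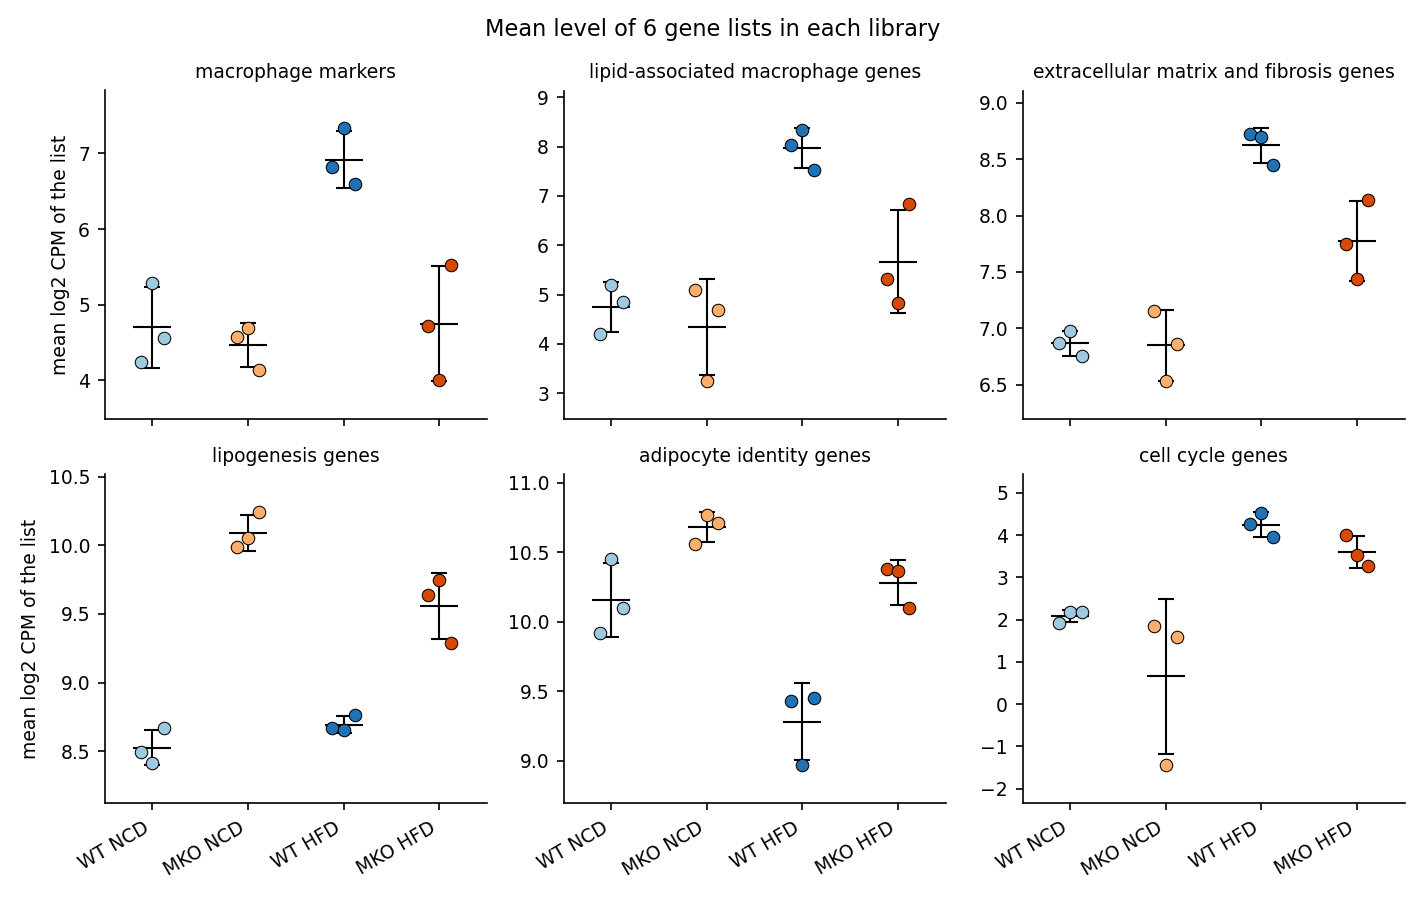
Mean log2 CPM of 6 gene lists in each library, with 1 point per library and bars for the mean ± SD of each group of 3. Macrophage markers lie at 6.60 to 7.33 in WT HFD and 3.996 to 5.52 in MKO HFD, and cell cycle genes at -1.45 in MKO NCD rep 2.

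Genes of the mature adipocyte were higher in MKO than WT fat on HFD. Adipocyte identity genes rose in 9 of 16 (11 in-list, median 0.83, camera adjusted p = 4.74e-11, 0.107 estimated). Resistin (Retn), a hormone of mouse adipocytes, was at 204 ± 106 CPM in WT and 1145 ± 302 CPM in MKO (log2 fold change 2.49, SE 0.37, adjusted p = 0.0108). Adrb3 was at 119 ± 76.1 and 723 ± 152 CPM (log2 fold change 2.60, SE 0.41, adjusted p = 0.0119), and Pck1 at 261 ± 33.1 and 765 ± 84.0 CPM (log2 fold change 1.55, SE 0.25, adjusted p = 0.0120). The lipid droplet coat protein Plin4 was at 2229 ± 210.5 and 4229 ± 296 CPM (log2 fold change 0.92, SE 0.12, adjusted p = 0.00945). Adiponectin (0.64, SE 0.27, adjusted p = 0.270) and leptin (-0.29, SE 0.32, adjusted p = 0.819) did not pass. Lipogenesis genes rose in 8 of 16 (14 in-list, median 0.90, camera adjusted p = 4.84e-12, 0.0763 estimated). The acyltransferase Gpam (1.03, SE 0.15, adjusted p = 0.00974) and the carboxylase Acaca, which makes malonyl-CoA (1.12, SE 0.18, adjusted p = 0.0114), rose. Acss2 (1.04, SE 0.18, adjusted p = 0.0147) and the lipid droplet protein Pnpla3 (1.64, SE 0.30, adjusted p = 0.0182) rose too. Insulin signalling genes rose in 4 of 12 (11 in-list, camera adjusted p = 5.01e-08, 0.0763 estimated). Irs1 (0.99, SE 0.13, adjusted p = 0.00945) and Slc2a4 (1.22, SE 0.20, adjusted p = 0.0129) are among them. Lipolysis genes rose in 3 of 10 (6 in-list, camera adjusted p = 1.48e-06, 0.107 estimated). The lipase Lipe (0.80, SE 0.16, adjusted p = 0.0257) and the droplet protein Plin1 (0.85, SE 0.14, adjusted p = 0.0129) rose. Oxidative phosphorylation genes moved up with 0 of 23 past the threshold over all genes and 11 in-list (median 0.44, camera adjusted p = 3.04e-08, 0.281 estimated). Endothelial markers did not pass (median 0.27, camera adjusted p = 0.308), though the vessel growth factor Vegfa rose (0.97, SE 0.20, adjusted p = 0.0302).

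Among the largest rises were Serpina1b (1.65 ± 0.517 to 153 ± 18.5 CPM, log2 fold change 6.53, SE 1.37, adjusted p = 0.0299) and Serpina1d (4.88, SE 1.04, adjusted p = 0.0308), genes of the antitrypsin family, whose similar sequences can share reads. Syt14, a vesicle protein, rose too (2.82, SE 0.39, adjusted p = 0.00945). The largest falls included Hs3st6, a chromosome 17 sulfotransferase (closing section) with 0 counts in MKO HFD (at least 32.6-fold lower, adjusted p = 0.0246). Slc37a2, a sugar-phosphate transporter of macrophages, fell (126 ± 55.9 to 12.2 ± 11.8 CPM, log2 fold change -3.37, SE 0.62, adjusted p = 0.0186). Of the 18 called genes of these adipocyte and largest-change paragraphs, 0 passed without MKO HFD rep 1 (adjusted p 0.0526 to 0.111) or MKO HFD rep 2 (0.0547 to 0.147). Of the same genes 6 passed without WT HFD rep 2, 7 without WT HFD rep 1 and 15 without WT HFD rep 3. Members of the adipocyte, lipogenesis and insulin lists past the threshold numbered 0 without MKO HFD rep 1 or 2, and of the lipolysis list 0 without these or WT HFD rep 1. Without WT HFD rep 1 and 2 the adipocyte count was 4 and 3, the lipogenesis count 1 and 1 and the insulin count 2 and 1. The insulin count was 2 without WT HFD rep 3. The lipolysis count was 1 without WT HFD rep 2 and 5 without MKO NCD rep 2. The oxidative phosphorylation count was 2 without MKO HFD rep 3 and 1 without MKO NCD rep 2. Hs3st6 also lost its call in a fit without the WT NCD group, and Serpina1b with no count filter.

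In all, 271 genes rose and 454 fell in MKO against WT on HFD. Called genes numbered 7 without MKO HFD rep 1, 13 without MKO HFD rep 2, 48 without WT HFD rep 2 and 175 without WT HFD rep 1. With MKO NCD rep 2 left out of the fit they numbered 1580. A fit of only these 6 libraries called 2260. The WT HFD libraries are also those of the diet comparison in WT, so the 2 comparisons are not independent.

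On NCD, MKO fat carried more transcripts for fatty acid synthesis than WT fat. Lipogenesis genes rose in 15 of 16 (16 in-list). Their median log2 fold change was 1.56 (camera adjusted p = 7.57e-21, 0.0279 estimated). Fatty acid synthase (Fasn) was at 1769 ± 703 CPM in WT and 9954 ± 1544 CPM in MKO (log2 fold change 2.49, SE 0.29, adjusted p = 0.00175). Acaca was at 494 ± 31.1 and 1663 ± 138 CPM (log2 fold change 1.75, SE 0.18, adjusted p = 9.67e-04). Acss2 was at 69.4 ± 15.9 and 358 ± 29.2 CPM (log2 fold change 2.37, SE 0.19, adjusted p = 2.90e-04). Me1 was at 369 ± 76.4 and 1514 ± 112 CPM (log2 fold change 2.04, SE 0.18, adjusted p = 4.29e-04). Dgat2, which makes the final bond of triglyceride, rose with them (1.53, SE 0.16, adjusted p = 0.00122). The lipogenesis count was 9 without WT NCD rep 1. Adipocyte identity genes rose in 2 of 16 (8 in-list, camera adjusted p = 5.69e-07, 0.221 estimated). They are Plin4 (0.66, SE 0.12, adjusted p = 0.0149) and Plin1 (0.68, SE 0.14, adjusted p = 0.0255). Plin4 lies on chromosome 17, where genes changed on both diets gathered, as given in the closing section. Leptin passed at 1.29, SE 0.32, adjusted p = 0.0489, and adiponectin did not (0.37, SE 0.26, adjusted p = 0.501). Leptin no longer passed with RLE size factors, no count filter, a mean of at least 1 CPM or sample weights.

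Genes that use fuel were higher too. Dilution of WT NCD fat by epididymis RNA stays open for these smaller rises (closing section). Glycolysis and hypoxia-response genes rose in 5 of 15 (8 higher and 1 lower in-list, camera adjusted p = 4.83e-04, 0.221 estimated). The glycolytic enzyme Aldoa rose from 727 ± 22.8 to 1357 ± 116 CPM (log2 fold change 0.90, SE 0.11, adjusted p = 0.00220). Ldha rose as well (0.73, SE 0.11, adjusted p = 0.00629). Fatty acid oxidation genes rose in 2 of 14 (10 in-list, camera adjusted p = 7.25e-07, 0.221 estimated). They are the electron carrier Etfdh (0.65, SE 0.12, adjusted p = 0.0151) and the acyl-carnitine enzyme Cpt2 (0.64, SE 0.15, adjusted p = 0.0457). Insulin signalling genes rose in 2 of 12 (8 in-list, camera adjusted p = 3.41e-06, 0.0799 estimated). The transcription factor Foxo1 is among them (0.73, SE 0.13, adjusted p = 0.0149). Lipolysis genes (1 of 10, 4 in-list, camera adjusted p = 9.46e-04, 0.221 estimated) moved up. So did endothelial markers (1 of 10, Cldn5, 0.98, SE 0.22, adjusted p = 0.0324, camera adjusted p = 9.62e-04, 0.447 estimated). Fabp5 rose (1.62, SE 0.21, adjusted p = 0.00236). Oxidative phosphorylation genes rose in 2 of 23 (9 in-list, median 0.36, camera adjusted p = 5.69e-07, 0.434 estimated). Sdha, a subunit of complex II, passed at an adjusted p of 0.0494. Cyc1, cytochrome c1, was raised mainly in 1 library (295, 3756 and 395 CPM in MKO NCD reps 1 to 3). Smpd1, the acid sphingomyelinase of lysosomes and among the largest rises, read 177, 1523 and 218 CPM. They were at 133 ± 10.1 and 86.3 ± 16.7 CPM in WT NCD (adjusted p = 0.0435 and 0.0457). Cpt2, Smpd1 and Sdha no longer passed with RLE size factors, these and Cyc1 with no count filter, Cyc1 and Smpd1 with limma-voom, and Cpt2, Cyc1 and Sdha with sample weights.

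Of the 18 called genes of these paragraphs 8 passed without WT NCD rep 1, 11 without MKO NCD rep 3 and 13 without WT NCD rep 3. Of them 14 passed without WT NCD rep 2 or MKO NCD rep 2 and 16 without MKO NCD rep 1. The genes lost without 1 library or more were Plin1, Plin4, Lep, Etfdh, Cpt2, Foxo1, Cldn5, Cyc1, Smpd1 and Sdha (adjusted p of lost genes 0.0531 to 0.147). Members of the adipocyte, fatty acid oxidation and insulin lists past the threshold numbered 0 without WT NCD rep 1 or MKO NCD rep 3, and those of the glycolysis list 2. The first 2 lists had 1 without WT NCD rep 3 or MKO NCD rep 2, and without WT NCD rep 3 or MKO NCD rep 1 the insulin list had 1 and the glycolysis list 3. Members of the oxidative phosphorylation list numbered 0 without WT NCD rep 1 or 3 and 1 without WT NCD rep 2 or MKO NCD rep 3, of the lipolysis list 3 without WT NCD rep 2 and 0 without WT NCD rep 1 or 3 or MKO NCD rep 2 or 3, and of the endothelial list 0 without WT NCD rep 1 or 2 or MKO NCD rep 1 or 3.

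Lower in MKO than WT fat on NCD were transcripts of the epididymis and of the acute stress response. Epididymis markers fell in 1 of 6 tested genes (4 in-list, camera adjusted p = 0.00176, 0.221 estimated). It is Crisp1, which fell from 3400 ± 1365 to 4.89 ± 7.61 CPM (log2 fold change -9.45, SE 1.60, adjusted p = 0.0104). The epididymal defensins Defb42 (at least 11460-fold, adjusted p = 2.90e-04) and Defb30 (at least 13020-fold, adjusted p = 0.00645) had 0 counts in MKO NCD. Akr1b7, an aldose reductase of the vas deferens, was at 9333 ± 8706 CPM in WT NCD with 9 counts over MKO NCD (adjusted p = 0.0117). Krt8 (-3.92, SE 0.60, adjusted p = 0.00629) and Plac8 (-4.98, SE 0.85, adjusted p = 0.0107) fell alongside. The prostaglandin synthase Ptgs2 fell from 967 ± 844 to 2.01 ± 2.495 CPM (log2 fold change -8.89, SE 1.88, adjusted p = 0.0267). Immediate early and heat shock genes fell in 3 of 12 (4 in-list, median -1.15, camera adjusted p = 0.00104, 0.221 estimated). The chaperone Hspa1a fell from 24.0 ± 10.7 to 3.65 ± 0.708 CPM (log2 fold change -2.72, SE 0.38, adjusted p = 0.00410). The nuclear receptor Nr4a1 fell as well (-2.303, SE 0.44, adjusted p = 0.0170). This count was 1 without WT NCD rep 1 or MKO NCD rep 3, and that of the epididymis list 4 without WT NCD rep 1. Akr1b7 lost its call without MKO NCD rep 1 or 3 and Nr4a1 without MKO NCD rep 3 or WT NCD rep 1. Ptgs2 lost its call without those 3 or WT NCD rep 2 (adjusted p of lost genes 0.0511 to 0.0812). Defb30, Akr1b7 and Ptgs2 no longer passed with limma-voom, with or without sample weights, and Akr1b7 and Ptgs2 with no count filter.

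Macrophage markers did not pass as a group between genotypes on NCD (0 of 18 past the threshold, median -0.11, camera adjusted p = 0.486). Nor did lipid-associated macrophage genes (camera adjusted p = 0.0703). Lyz2 (-0.20, SE 0.38, adjusted p = 0.813), Adgre1 (0.41, SE 0.52, adjusted p = 0.715), Mrc1 (0.25, SE 0.30, adjusted p = 0.693) and Trem2 (-0.87, SE 1.12, adjusted p = 0.721) did not pass either. Matrix genes had 3 higher and 2 lower of 19 in-list. Their log2 fold changes had a median of 0.38 and a mean of -0.01 (camera adjusted p = 0.00503, 0.440 estimated). Calls lost without 1 of several libraries were those for B cell markers, lower (median -1.93, camera adjusted p = 0.0353, 0.618 estimated) and mitophagy and autophagy genes, higher (median 0.09, camera adjusted p = 0.0382, 0.515 estimated). The call for skeletal muscle markers, lower, was another (median -2.84, camera adjusted p = 0.0458, 0.440 estimated). The B cell call was lost without WT NCD rep 1, 2 or 3 or MKO NCD rep 2 (camera adjusted p = 0.0790, 0.0705, 0.0602 and 0.102, medians -2.155 to -1.338). The mitophagy call was lost without WT NCD rep 1 or 3 or MKO NCD rep 2 (camera adjusted p = 0.0655, 0.186 and 0.0677, medians -0.00578 to 0.0798). The muscle call was lost without WT NCD rep 1 or 2 or any MKO NCD library (camera adjusted p = 0.249, 0.0893, 0.179, 0.217 and 0.0919, medians -3.177 to -1.447).

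In all, 450 genes rose and 432 fell in MKO against WT on NCD. Called genes numbered 391 without MKO NCD rep 3, 415 without WT NCD rep 1 and 572 without WT NCD rep 2. With RLE size factors 302 rose and 440 fell. A fit of only these 6 libraries called 53. The 2 genotype comparisons share no library. Of their called genes 92 rose on both diets (6.01 expected from independent calls), 25 fell on both (9.66 expected), 2 rose on NCD and fell on HFD, and 1 did the reverse.

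Averaged over diets, MKO fat had more transcripts of lipid storage and insulin action. Lipogenesis genes rose in 15 of 16 (16 in-list, median 1.14, camera adjusted p = 1.53e-21, 0.0219 estimated). Acss2 (1.71, SE 0.13, adjusted p = 1.91e-04), Acaca (1.44, SE 0.13, adjusted p = 3.88e-04), Me1 (1.21, SE 0.12, adjusted p = 7.88e-04) and Dgat2 (1.14, SE 0.11, adjusted p = 7.88e-04) rose. Insulin signalling genes rose in 10 of 12 (11 in-list, camera adjusted p = 2.93e-09, 0.0219 estimated). Slc2a4 (0.91, SE 0.14, adjusted p = 0.00496) and Irs1 (0.67, SE 0.09, adjusted p = 0.00298) rose. So did Foxo1 (0.56, SE 0.10, adjusted p = 0.00760). The insulin count was 5 without WT HFD rep 2 and 6 without WT HFD rep 3 or MKO HFD rep 2. Adipocyte identity genes rose in 9 of 16 (14 in-list, median 0.66, camera adjusted p = 1.41e-12, 0.131 estimated). Retn (1.60, SE 0.25, adjusted p = 0.00518), Plin1 (0.77, SE 0.10, adjusted p = 0.00204) and Plin4 (0.79, SE 0.09, adjusted p = 9.59e-04) rose. Pparg, the master regulator of the adipocyte, rose with them (0.70, SE 0.13, adjusted p = 0.00984). Lipolysis genes rose in 6 of 10 (8 in-list, camera adjusted p = 1.34e-06, 0.131 estimated). Lipe (0.64, SE 0.11, adjusted p = 0.00914) and Adrb3 (1.65, SE 0.28, adjusted p = 0.00748) rose. The count was 3 without WT NCD rep 3, WT HFD rep 2 or 3, or MKO HFD rep 1 or 2. Oxidative phosphorylation genes rose in 8 of 23 (18 in-list, camera adjusted p = 5.82e-11, 0.279 estimated). Sdha is among them (0.49, SE 0.10, adjusted p = 0.0150). The count was 1 without WT HFD rep 2 or MKO HFD rep 1 or 2, 3 without WT NCD rep 1 or 3, MKO NCD rep 3 or WT HFD rep 3, 5 without WT HFD rep 1 and 14 without WT NCD rep 2.

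Fatty acid oxidation genes had 3 of 14 higher (camera adjusted p = 3.71e-04, 0.318 estimated), 1 without WT NCD rep 1 and 0 without MKO NCD rep 3, WT HFD rep 2 or 3, or MKO HFD rep 1 or 2. Glycolysis and hypoxia-response genes had 5 higher and 1 lower of 15 (camera adjusted p = 0.00603, 0.323 estimated). Aldoa rose (0.47, SE 0.08, adjusted p = 0.00649). The higher count was 2 without MKO HFD rep 2 and 3 without WT NCD rep 1 or 3, MKO NCD rep 3 or WT HFD rep 2 or 3. The lower count was 0 without any 1 library except MKO NCD rep 2. Endothelial markers had 1 of 10 higher (camera adjusted p = 0.00418, 0.535 estimated), and 0 without MKO NCD rep 3, WT HFD rep 1 or 2, or MKO HFD rep 1. Vegfa rose as well (0.75, SE 0.14, adjusted p = 0.0126). Macrophage markers, with a median genotype effect of -0.11 on NCD and -2.14 on HFD, fell in 6 of 18 (17 in-list, median -1.02, camera adjusted p = 1.34e-06, 0.368 estimated). Csf1r (-0.89, SE 0.21, adjusted p = 0.0296) and Lyz2 (-1.18, SE 0.28, adjusted p = 0.0284) fell. The count was 0 without MKO NCD rep 3, WT HFD rep 1 or 2, or MKO HFD rep 1 or 2. It was 1 without WT NCD rep 2, 2 without MKO NCD rep 1, 3 without WT HFD rep 3, 11 without WT NCD rep 1 and 13 without MKO HFD rep 3. Lipid-associated macrophage genes had 1 higher and 3 lower of 17 (camera adjusted p = 0.0107, 0.567 estimated). Cd9 (-1.22, SE 0.20, adjusted p = 0.00567) and Ctsk (-1.15, SE 0.23, adjusted p = 0.0162) fell and Fabp5 rose (0.73, SE 0.14, adjusted p = 0.0140), with 6 lower without MKO HFD rep 3 and 2 higher without WT NCD rep 2. Mast cell markers fell in 1 of 6 (5 in-list, camera adjusted p = 0.00418, 0.251 estimated). Cma1, the mast cell chymase, was at 13.4 ± 8.14 and 4.46 ± 0.815 CPM on NCD and 9.13 ± 3.43 and 2.74 ± 1.04 CPM on HFD (log2 fold change -1.66, SE 0.33, adjusted p = 0.0154). The mast cell count was 4 without MKO NCD rep 2 and 0 without MKO HFD rep 2. Immediate early and heat shock genes fell in 3 of 12 (camera adjusted p = 0.00109, 0.222 estimated). The AP-1 subunit Junb fell (-1.61, SE 0.35, adjusted p = 0.0211). The count was 0 without MKO NCD rep 3, WT HFD rep 2 or MKO HFD rep 2. Monocyte and neutrophil markers fell in 2 of 8 (camera adjusted p = 0.00418, 0.222 estimated), and 1 without WT HFD rep 3 or MKO HFD rep 2. B cell markers moved down (6 of 10 lower in-list, camera adjusted p = 0.00483, 0.535 estimated). Epididymis markers (0 of 6 lower, camera adjusted p = 0.0147, 0.368 estimated) and Krt8 (-2.45, SE 0.40, adjusted p = 0.00650) carry the transcripts of the WT NCD libraries. Cell cycle genes moved down (camera adjusted p = 0.0178, 0.535 estimated), a call lost without WT HFD rep 2 (camera adjusted p = 0.0743) or MKO HFD rep 3 (0.0728).

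Among the largest rises were 3 pseudogenes of the ribosomal protein gene Rps2, whose reads can come from related sequences. Rps2-ps6 was at 2.89 ± 0.284 and 2.56 ± 0.191 CPM in WT NCD and WT HFD and 14.6 ± 2.47 and 14.3 ± 0.211 CPM in MKO NCD and MKO HFD (log2 fold change 2.41, SE 0.16, adjusted p = 1.68e-04). Rps2-ps8 on chromosome 17 (2.74, SE 0.29, adjusted p = 8.49e-04) and Rps2-ps13 (2.16, SE 0.18, adjusted p = 2.93e-04) rose. Serpina1b rose as well (3.84, SE 0.86, adjusted p = 0.0241). Among the largest falls, the cadherin Cdh17 was at 12.6 ± 8.45, 0, 0.109 ± 0.189 and 0 CPM in WT NCD, MKO NCD, WT HFD and MKO HFD (adjusted p = 0.0280). Ankrd22 was at 4.25 ± 4.07, 0, 0.290 ± 0.256 and 0 CPM (adjusted p = 0.0154). In all, 820 genes rose and 653 fell, and 647 rose and 729 fell with RLE size factors. DESeq2 called 1218 higher and 1892 lower. Called genes numbered 614 without MKO HFD rep 2, 673 without WT HFD rep 2 and 780 without MKO HFD rep 1. They numbered 931 without WT HFD rep 1, 972 without MKO NCD rep 3, and 2378 without MKO NCD rep 2. Of the 30 genes named here, 24 passed without MKO HFD rep 2, 25 without WT HFD rep 2, 26 without MKO HFD rep 1 or MKO NCD rep 3, and 27 without WT HFD rep 1. Of them 28 passed without WT HFD rep 3 or WT NCD rep 2, and 29 without MKO NCD rep 1 or WT NCD rep 1. The genes lost were Lyz2, Csf1r, Cdh17, Serpina1b, Junb and Cma1 (adjusted p of lost genes 0.0508 to 1). Junb, Cma1 and Cdh17 no longer passed with limma-voom and Serpina1b with no count filter.

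In MKO fat on HFD, genes of dividing cells and of matrix rose and no macrophage marker passed the threshold. Cell cycle genes rose in 2 of 14 (9 in-list, median 2.48, camera adjusted p = 9.83e-08, 0.470 estimated). Mki67 rose from 9.60 ± 3.26 to 54.9 ± 22.1 CPM (log2 fold change 2.52, SE 0.35, adjusted p = 0.00913) and Top2a rose too (2.38, SE 0.29, adjusted p = 0.00488). The cell cycle inhibitor Cdkn1a, among the largest rises of all genes, went from 12.4 ± 3.82 to 111 ± 3.25 CPM (log2 fold change 3.17, SE 0.23, adjusted p = 5.06e-04). The count was 10 without MKO NCD rep 2, whose cell cycle genes read lowest of all libraries. Matrix genes rose in 6 of 19 (10 in-list, median 0.76, camera adjusted p = 5.78e-05, 0.482 estimated). The collagen Col6a1 rose from 235 ± 105 to 790.3 ± 184 CPM (log2 fold change 1.75, SE 0.29, adjusted p = 0.0160). Col5a1 (1.06, SE 0.18, adjusted p = 0.0166) and the collagen-binding protein Sparc (0.95, SE 0.18, adjusted p = 0.0280) rose too. Macrophage markers did not pass as a group (0 of 18, median 0.35, camera adjusted p = 0.991). Lipid-associated macrophage genes did not either (median 0.72, camera adjusted p = 0.0812). Lyz2 (0.23, SE 0.38, adjusted p = 0.823), Adgre1 (0.06, SE 0.52, adjusted p = 0.978), Mrc1 (0.07, SE 0.30, adjusted p = 0.938) and Trem2 (2.23, SE 1.15, adjusted p = 0.351) did not pass either. Ccl2 rose from 2.66 ± 1.48 to 13.1 ± 5.19 CPM (log2 fold change 2.30, SE 0.45, adjusted p = 0.0315).

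Lipogenesis genes fell in 3 of 16 (8 lower and 1 higher in-list, median -0.46, camera adjusted p = 7.69e-05, 0.470 estimated). Acaca fell from 1663 ± 138 to 510.4 ± 132 CPM (log2 fold change -1.70, SE 0.18, adjusted p = 0.00249). The citrate lyase Acly (-1.56, SE 0.25, adjusted p = 0.0147) and Acacb, the carboxylase that restrains fat oxidation (-1.79, SE 0.32, adjusted p = 0.0200), fell too. Fasn did not pass (-1.23, SE 0.28, adjusted p = 0.0539). Adipocyte identity genes fell in 2 of 16 (5 in-list, camera adjusted p = 0.00402, 0.751 estimated). Cfd fell from 8389 ± 2664 to 1600 ± 623 CPM (log2 fold change -2.39, SE 0.48, adjusted p = 0.0327). Pck1 fell as well (-1.25, SE 0.25, adjusted p = 0.0322). Without MKO NCD rep 2 that list gave a camera adjusted p of 0.115. Its members past the threshold numbered 0 without MKO NCD rep 2 or 3 or any 1 MKO HFD library, and those of the lipogenesis list 1 without MKO NCD rep 3 or MKO HFD rep 1 or 3. Insulin signalling genes (6 lower and 1 higher of 12 in-list, camera adjusted p = 0.00755, 0.470 estimated) lost their call without MKO NCD rep 2 (camera adjusted p = 0.126). Oxidative phosphorylation genes (median -0.16, camera adjusted p = 0.0107, 0.751 estimated) lost theirs without MKO NCD rep 2 (camera adjusted p = 0.126), MKO NCD rep 3 (0.0745) or MKO HFD rep 3 (0.251). B cell markers (1 of 10 higher, Ighm, the heavy chain of IgM, 2.199, SE 0.43, adjusted p = 0.0315, camera adjusted p = 0.0325, 0.751 estimated) gave a camera adjusted p of 0.154 without MKO NCD rep 2 and 0.0598 without the WT NCD group. Leptin did not pass (1.09, SE 0.32, adjusted p = 0.118). Gpx3 fell (-1.88, SE 0.29, adjusted p = 0.0126) and the mitochondrial superoxide dismutase Sod2 rose (0.61, SE 0.10, adjusted p = 0.0182). Among the largest changes were rises of Tph2 (0.225 ± 0.390 to 31.0 ± 39.4 CPM, log2 fold change 7.15, SE 1.27, adjusted p = 0.0208) and the choline transporter Slc5a7 (3.498 ± 3.65 to 138 ± 79.3 CPM, log2 fold change 5.31, SE 1.07, adjusted p = 0.0336). The proteoglycan Ncan rose (4.65 ± 1.04 to 44.0 ± 5.10 CPM, log2 fold change 3.24, SE 0.36, adjusted p = 0.00326). Among the largest falls were those of Rassf6, a tumour suppressor (-4.68, SE 0.59, adjusted p = 0.00531), and the cytochrome Cyp2f2 (-4.04, SE 0.70, adjusted p = 0.0187).

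In all, 212 genes rose and 196 fell on HFD in MKO. Called genes numbered 75 without MKO HFD rep 2, 93 without MKO HFD rep 3, 100 without MKO NCD rep 3 and 129 without MKO HFD rep 1. A fit of only these 6 libraries called 41. Of the 20 called genes named here, 7 passed without MKO HFD rep 3 or MKO NCD rep 3, 9 without MKO HFD rep 2 and 11 without MKO HFD rep 1. Of them 15 passed without MKO NCD rep 2 and all but Ccl2 without MKO NCD rep 1 (adjusted p of lost genes 0.0510 to 0.1253). Those that passed without any 1 library were Mki67, Top2a, Cdkn1a, Acaca, Ncan and Rassf6. Ccl2, Tph2 and Cyp2f2 no longer passed with limma-voom, Tph2 and Slc5a7 with no count filter, and Tph2 with sample weights. Matrix genes past the threshold numbered 0 without MKO NCD rep 3 or MKO HFD rep 3, and 3, 2 and 1 without MKO NCD rep 2, MKO HFD rep 1 and MKO HFD rep 2. The 2 diet comparisons share no library. Of their called genes 178 rose on HFD in both genotypes (20.1 expected from independent calls), 143 fell in both (16.2 expected), and 2 went opposite ways. Over all tested genes the log2 fold changes for diet in WT and MKO correlated at r = 0.55 (Spearman 0.48), with a median absolute value of 0.559 in WT and 0.402 in MKO.

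**Figure D4:**
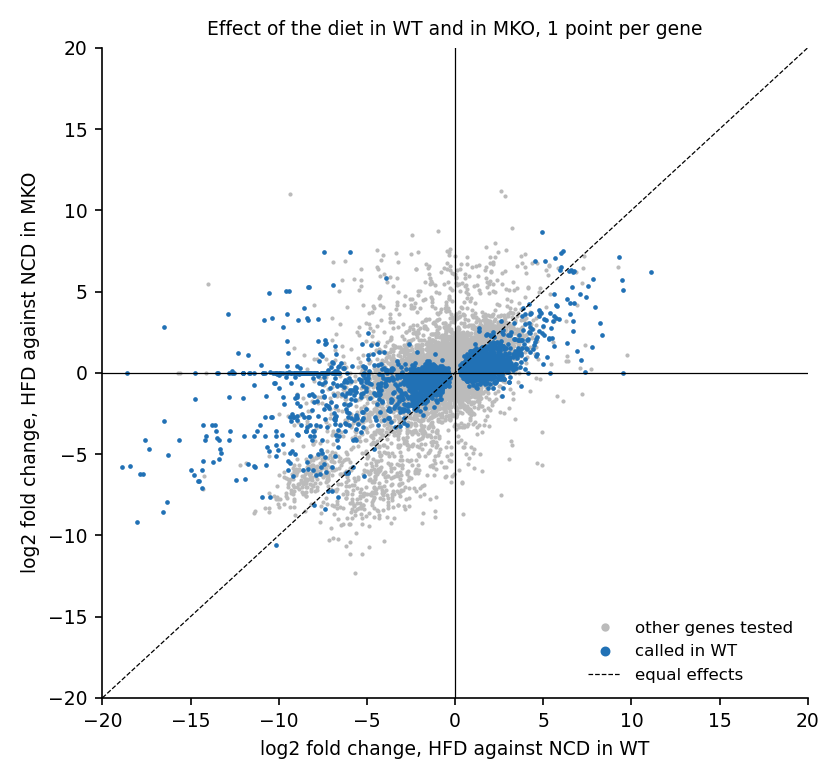
Log2 fold change of HFD against NCD in WT (horizontal axis) and in MKO (vertical axis), 1 point per tested gene, with genes called in WT in blue. Over all tested genes the median absolute change is 0.559 in WT and 0.402 in MKO.

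Macrophage and matrix genes had a lower diet effect in MKO than in WT as groups. This held for macrophage markers (median -1.89, camera adjusted p = 1.67e-13, 0.203 estimated). Of their 18 members 15 were lower in-list and 0 over all genes (7 without MKO HFD rep 3). Lipid-associated macrophage genes had a lower diet effect too (1 of 17 lower, 8 in-list, median -1.81, camera adjusted p = 5.52e-11, 0.184 estimated), as did matrix genes (2 of 19 lower, 13 in-list, median -1.15, camera adjusted p = 3.14e-10, 0.184 estimated). Without MKO HFD rep 3, 8 and 7 members of these 2 lists were lower. The first numbered 2 and 3 without WT NCD rep 2 and WT HFD rep 3, and 0 without WT NCD rep 1, MKO NCD rep 1 or 3, WT HFD rep 1 or 2 or MKO HFD rep 2. Matrix genes numbered 1 without any 1 WT NCD library or MKO NCD rep 1, and 0 without MKO NCD rep 3, WT HFD rep 1 or 2 or MKO HFD rep 1 or 2. Apobec1, an RNA editing enzyme of macrophages, went from 16.0 ± 2.46 to 153 ± 28.5 CPM in WT and from 23.4 ± 3.41 to 31.7 ± 8.92 CPM in MKO (log2 fold change -2.81, SE 0.31, adjusted p = 0.00983). The taurine transporter Slc6a6 (-2.80, SE 0.35, adjusted p = 0.0181), the cytokine receptor subunit Csf2rb2 (-2.41, SE 0.40, adjusted p = 0.0428) and Sirpa, a receptor that restrains phagocytes (-2.23, SE 0.36, adjusted p = 0.0408), had the same direction. So did Stab1 (-1.35, SE 0.21, adjusted p = 0.0304), Tgfb1 (-1.27, SE 0.17, adjusted p = 0.0225) and Col3a1 (-1.77, SE 0.31, adjusted p = 0.0489). Plin2, a lipid droplet protein of lipid-laden cells, went from 161 ± 32.5 to 1052 ± 254 CPM in WT and from 356 ± 30.03 to 517 ± 96.7 CPM in MKO (log2 fold change -2.17, SE 0.30, adjusted p = 0.0261). Fabp5 (-1.78, SE 0.29, adjusted p = 0.0368) and Me1 (-1.66, SE 0.24, adjusted p = 0.0261) were already higher in MKO than WT on NCD.

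Among the largest values above 0 were genes high in WT NCD alone, the libraries with epididymis transcripts. Gldc, which cleaves glycine, was at 106 ± 31.2, 1.91 ± 0.885, 2.82 ± 0.616 and 1.71 ± 0.0810 CPM in WT NCD, MKO NCD, WT HFD and MKO HFD (log2 fold change 5.07, SE 0.47, adjusted p = 0.00753). Cd52, a surface glycoprotein of leukocytes and epididymis, was at 543 ± 225, 10.4 ± 2.79, 47.2 ± 10.3 and 12.1 ± 4.42 CPM (log2 fold change 3.73, SE 0.49, adjusted p = 0.0225). The transcription factor Emx2 (4.49, SE 0.65, adjusted p = 0.0261), the DNA repair gene Fanca (4.39, SE 0.72, adjusted p = 0.0428), the desaturase Fads2 (3.49, SE 0.61, adjusted p = 0.0496) and Hspa1a (3.45, SE 0.52, adjusted p = 0.0294) had the same pattern. Epididymis markers had a higher diet effect in MKO as a list (camera adjusted p = 0.00436, 0.274 estimated). In all, 24 genes had a higher and 29 a lower diet effect in MKO. The count was 2 without WT HFD rep 1 or 2, 4 without MKO NCD rep 3, 8 without MKO HFD rep 1 or 2, and 19 without MKO NCD rep 1. It was 28 without WT NCD rep 1, 108 without WT NCD rep 3, 191 without MKO NCD rep 2 and 288 without MKO HFD rep 3. Hspa1a, Fads2, Fanca and Emx2 no longer passed with limma-voom, Fads2 with no count filter, and Col3a1 with RLE size factors. Of the 16 genes named, 1 passed without WT HFD rep 2, 2 without WT HFD rep 1 or MKO NCD rep 3, 3 without MKO HFD rep 1, and 4 without MKO HFD rep 2. Of them 5 passed without MKO NCD rep 1, 7 without WT NCD rep 1, 8 without WT NCD rep 2, 13 without WT HFD rep 3 and 15 without WT NCD rep 3.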

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

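The tests in this part of epididymis tissue, exchanged labels, dilution, adipocyte RNA, single libraries and macrophage subtypes were chosen after the result was seen, and the regroupings of libraries were planned before their result.

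The diet effect differed between genotypes in 53 genes (edgeR quasi-likelihood interaction, Benjamini-Hochberg adjusted p under 0.05), a difference between groups that the diet comparisons of each genotype do not test. The interaction log2 fold change was -2.81 for Apobec1, -2.80 for Slc6a6, -2.41 for Csf2rb2, -2.23 for Sirpa, -2.17 for Plin2, -1.78 for Fabp5, -1.775 for Col3a1, -1.66 for Me1, -1.35 for Stab1 and -1.27 for Tgfb1. It was 3.45 for Hspa1a, 3.49 for Fads2, 3.73 for Cd52, 4.39 for Fanca, 4.49 for Emx2 and 5.07 for Gldc, the genes high in WT NCD alone. The camera adjusted p of the interaction was 1.67e-13 for macrophage markers, 5.52e-11 for lipid-associated macrophage genes, 3.14e-10 for matrix genes, 3.22e-06 for lipogenesis genes, 3.56e-05 for fatty acid oxidation genes, 4.04e-04 for fibroblast and progenitor markers, 5.99e-04 for interferon-stimulated genes and 0.00180 for resident macrophage genes. It was 0.00436 for epididymis markers, 0.00480 for glycolysis genes, 0.0212 for thermogenic genes, 0.0271 for mitophagy genes and 0.0310 for endothelial markers, and with an estimated correlation these 13 lists had an adjusted p between 0.184 and 0.639. The mitophagy call was lost without WT NCD replicate 3 (camera adjusted p = 0.143) or MKO NCD replicate 2 (0.0843). The endothelial call was lost without WT NCD replicate 2 (camera adjusted p = 0.326), MKO NCD replicate 1 (0.0571), MKO NCD replicate 3 (0.169), WT HFD replicate 3 (0.0938) or MKO HFD replicate 3 (0.0733).

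Of 100 regroupings of the libraries, drawn from 200 with genotypes reassigned within each diet, 3 gave as many interaction genes as the real grouping, which called 53, the real one included. The highest other count, 1473, is the regrouping that exchanges WT and MKO on HFD, which turns the interaction into the genotype difference shared by the diets and points to a structure of the samples. Of the same regroupings 19 gave as many interaction lists as the real 13 (highest other 21) and 7 as many lists as the real 16 averaged over diets (highest other 21), so chance is not excluded for those 2 counts of lists. For genes averaged over diets 1 of 100, the real one, gave as many as 1473 (highest other 100). The 10 regroupings of 6 libraries are too few for a share under 0.05. The real and highest other counts of genes were 882 and 0 for MKO against WT on NCD, 725 and 1 on HFD, 3610 and 0 for HFD against NCD in WT and 408 and 0 in MKO, each with 1 regrouping as large, the real one. For lists they were 14 and 16 (3 as large), 17 and 15 (1), 16 and 15 (1) and 7 and 10 (4).

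Epididymis transcripts stand in the WT NCD libraries alone, and WT NCD is on 1 side of the NCD genotype comparison, the WT diet comparison and the interaction. Tissue of the adjoining epididymis taken with the fat could account for this, since 5 of 9 measured markers were higher in each WT NCD library than in each of the other 9 libraries, which leaves it open. An exchange of single libraries with another group is argued against by the highest summed level elsewhere, 16.97 CPM, against at least 4788 CPM in WT NCD, and of all 3 labels with MKO NCD or WT HFD by the 2.5% of 120 genes called by genotype on both diets and 0.619% of 323 called by diet in both genotypes that went opposite ways, while an exchange with MKO HFD would keep this agreement and stays open. Dilution by epididymis RNA as the cause of the lower lipogenesis genes in WT NCD is argued against by the adipocyte identity genes, whose upper quartile of log2 fold change for MKO against WT was 0.6678, below the lipogenesis median of 1.56 and lower quartile of 1.298. A biological difference in what the WT NCD samples hold was not tested.

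Macrophage genes were lower in MKO than WT fat on HFD. A larger share of adipocyte RNA in MKO could lower all other cell types alike, but per library macrophage markers fell further than endothelial (log2 difference -2.351, 95% interval -4.044 to -0.6577), fibroblast (-1.534, -2.571 to -0.4975) and T and NK cell markers (-1.405, -2.43 to -0.3796; t test, each adjusted p = 0.0444 over 7 cell types), which argues against it as the whole cause, while mesothelial, red blood cell, B cell and mast cell markers did not pass (0.105 to 0.624) and a part in the fall stays open. A single library as the source is argued against by the gap of 1.079 between the lowest WT HFD and the highest MKO HFD library in mean log2 CPM, though 0 of 18 members passed without WT HFD replicate 2 or MKO HFD replicate 1 or 2 and camera with an estimated correlation gave an adjusted p of 0.107. A loss of lipid-associated macrophages alone stays open, since these cells also carry macrophage markers. Resident macrophage genes had a lower quartile of -1.51, above the macrophage markers' upper quartile, -1.74. Yet all MKO HFD libraries (mean log2 CPM 2.77 to 3.76) lay below WT HFD (4.22 to 4.43) in them, against such a loss alone. Fewer macrophages in MKO fat on HFD stays open as a hypothesis, found and tested on the same data, beside lower transcription per macrophage, which was not tested.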

How the results depend on the processing

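Tests with sample weights, without MKO NCD replicate 2 in comparisons that do not use it and without the WT NCD group were added after the data were seen, and all other alternatives were planned. No called change of a named gene, Bnip3 value or diet correlation changed sign under an alternative run, and where a count moved the cause was not tested. The median of the mitophagy list on NCD, 0.0921, was -0.00578 without WT NCD replicate 3. RLE and upper-quartile size factors, no count filter, a mean of at least 1 CPM and no robust spread moved no total count of genes by over 1.5 times, and higher calls for diet in MKO fell from 212 to 140 with no filter. With RLE factors, higher calls on NCD fell from 51.0 to 40.7% (302 of 742), averaged from 55.7 to 47.0%, for diet in WT from 53.4 to 48.9% and in MKO from 51.96 to 48.2%, and with upper-quartile factors the diet shares were 45.6 and 42.2%. DESeq2 called 2349 genes for MKO against WT on NCD, 1738 on HFD, 1796 for diet in MKO, 1162 for the interaction and 3110 averaged, and Bnip3, HFD against NCD in MKO, passed in it (-0.5355, DESeq2 adjusted p = 0.0431). Simulated data of 19635 genes were built from the levels and spread of all 12 libraries, with the changes placed in MKO HFD. In them edgeR recovered 16% of 2-fold and 45% of 4-fold changes with 4 false calls. There limma-voom recovered 13 and 42% with 2, and DESeq2, with 20156 genes, 32 and 57% with 56. limma-voom called 1417 genes on NCD and 176 for the interaction, and with sample weights 1448 on NCD, 3676 on HFD, 6255 for diet in WT, 1381 for diet in MKO, 879 for the interaction and 3432 averaged.

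A fold of at least 2 left 473 genes on NCD, 456 on HFD, 2086 for diet in WT, 218 for diet in MKO and 490 averaged. A fit of only the 6 libraries called 53 on NCD, 2260 on HFD and 41 for diet in MKO. A block by replicate number called 482 on NCD, 262 on HFD, 160 for diet in MKO, 12 for the interaction and 834 averaged. The numbers do not pair the samples by design, 18 same-numbered pairs correlated at -0.143 to 0.165 after removal of group means, 3 of them over 0.1, and 4 of 12 libraries matched their own number best. Camera with an estimated correlation called 1 list on NCD, 0 on HFD, 0 for diet in WT, 0 for diet in MKO, 0 for the interaction and 2 averaged, where genes with an unadjusted edgeR p under 0.05 numbered 3060 on HFD, 6393, 3457 and 2652, and fry called 12, 17, 7 and 5 lists there. The diet effects of the genotypes correlated at 0.3531 with no count filter, 0.3598 with DESeq2 and 0.6168 over genes changed in WT.

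Leaving out 1 library gave 391 to 1028 genes on NCD, 7 to 1580 on HFD, 1884 to 6789 for diet in WT, 75 to 480 for diet in MKO, 2 to 288 for the interaction and 614 to 2378 averaged, and 6 to 13 lists for diet in MKO. The correlation ranged from 0.3704 to 0.5423, and Bnip3 from -0.6241 to -0.3168 for diet in MKO, -0.422 to -0.1338 in WT, -0.3889 to -0.04327 for the interaction, 0.2178 (without MKO NCD replicate 2) to 0.5633 on NCD, 0.1072 to 0.2337 on HFD and 0.1961 to 0.3689 averaged. Of 279 called values of named genes, 110 passed without any 1 library (0 of 48 on HFD, 62 of 85 for diet in WT), and 269 passed with RLE factors, 230 with no filter, 243 with limma-voom, 256 with sample weights, 186 with the block and all 274 tested with DESeq2. Alternatives for normalized tables were not applicable to counts.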

Other observations

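The hypothesis on chromosome 17 below had 3 tests. The correlation of genotype effects was planned before its result was seen. The count near Bnip3, the excess per chromosome and the 45 Mb bound were chosen after.

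T and NK cell markers did not pass as a group on HFD in WT (camera adjusted p = 0.0673), though Il7r, the receptor of the lymphocyte growth factor IL-7, rose (4.91, SE 1.26, adjusted p = 0.0219). B cell markers did not pass either (camera adjusted p = 0.0737), and Ighm rose (2.19, SE 0.43, adjusted p = 0.00573). Mitophagy and autophagy genes had 4 of 19 higher (camera adjusted p = 0.229), among them the mitophagy receptor Optn (1.55, SE 0.19, adjusted p = 5.32e-04). Unfolded protein response genes went both ways (camera adjusted p = 0.214), with Herpud1, which serves protein degradation, lower (-0.77, SE 0.14, adjusted p = 0.00298) and the stress transcription factor Ddit3 higher (0.57, SE 0.12, adjusted p = 0.00944). Dio2, a thermogenic gene that activates thyroid hormone, rose (3.98, SE 0.93, adjusted p = 0.0142). Mesothelial markers had 3 lower (camera adjusted p = 0.297), with the keratin Krt19 among them (-3.12, SE 0.69, adjusted p = 0.0102). Skeletal muscle (camera adjusted p = 0.158), mast cell (0.571), red blood cell (0.340), oxidative phosphorylation (0.112) and immediate early genes (0.499) did not pass. Between genotypes on NCD, T and NK cell (camera adjusted p = 0.844), mesothelial (0.311), unfolded protein (0.879), oxidative stress (0.879), thermogenic (0.0509), mast cell (0.0709) and cell cycle genes (0.124) did not pass.

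Genes changed the same way by genotype on both diets gathered on chromosome 17, which held 20 of the 117 such genes, against 5.779 expected from the tested genes (hypergeometric test, Benjamini-Hochberg adjusted p = 2.42e-05 over chromosomes), 19 of them in its first 45 Mb. An effect of the knockout spread over the genome stays open, since the other 97 genes lie on other chromosomes. A strain segment around Bnip3 on chromosome 7 stays open and would not account for genes on chromosome 17, and the 0 of 184 tested genes within 10 Mb of Bnip3, with 1.063 expected, are too few to decide. A segment of another strain on chromosome 17 in 1 genotype cannot be told apart from other causes. The genotype effects of the 625 other genes of the segment correlated between diets at 0.2409, above the median of 0.208 over the 19 other chromosomes with at least 200 tested genes and below their highest, 0.3476.

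The next genes were chosen after their values were seen, for chromosome 17 or known strain differences. On chromosome 17, the genotype log2 fold change of Uhrf1bp1 was 1.72 on NCD and 1.00 on HFD (edgeR adjusted p = 0.00160 and 0.0236). Paqr4 had 1.29 and 1.57 (0.00220 and 0.00446) and Rnps1 -1.24 and -0.94 (0.00430 and 0.0192). Nnt, a mitochondrial transhydrogenase on chromosome 13, read 15.9 to 24.2 CPM in the WT and 29.6 to 64.3 CPM in the MKO libraries (log2 fold change averaged over diets 1.03; edgeR adjusted p = 5.49e-04). Rps2 did not pass (-0.46, SE 0.13, adjusted p = 0.0520), and its pseudogenes named above and Rps2-ps10 (1.27, SE 0.17, adjusted p = 0.00204) rose, while Rps2-ps5 and Rps2-ps4 did not pass (adjusted p = 0.353 and 0.970).

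In MKO NCD replicate 2, 58.3% of the 2151 genes at 1 to 3 CPM in the other 2 libraries of its group read 0, against 0.105 to 8.73% for the same measure in the other libraries. The authors' deposited table calls 520 genes higher and 1222 lower in MKO on NCD, among 22493 with an adjusted p, and 1333 and 2083 on HFD, among 19651. Of the genes called here 806 of 882 on NCD and 725 of 725 on HFD are called in that table in the same direction. It gives Bnip3 folds of 1.278 and 1.129 (deposited adjusted p = 0.47 and 0.378).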
